A study of Drosophila melanogaster with 34 samples.

How the data were processed

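Gene expression was measured on Affymetrix arrays of a Drosophila melanogaster design, hybridised with biotin-labelled cDNA amplified from total RNA of pooled first-instar larvae. The labels state that 35 samples were hybridised, and 34 arrays were analysed here. The deposited values are log2 expression per probe set, which the authors made with GCRMA and the affy package, per the submitters' processing notes; versions are not given in the sources used here. GCRMA corrects each probe for background by its GC content, normalizes arrays to a common distribution and summarises the probes of a set, so values near the floor reflect the background model and changes toward it are compressed or stretched by it. The unit was checked on the values, whose medians lay between 3.89 and 4.02 on every array. Scanner values were not used here.

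Regime, population, exposure and extraction day were taken from the titles and descriptions of the samples. The labels say that RNA was extracted in 3 blocks on different days with 1 sample per population and exposure in each, and the number 1, 2 or 5 that ends each title was read as that day. Deviations from the population and exposure means correlated on average at 0.394, 0.184 and 0.423 between arrays of day 1, 2 and 5, and at -0.196 between arrays of different days. Part of this negative value is built in, since deviations of arrays that share a mean sum to 0. Between days 5 and 1, 4204 probe sets differed. The day is therefore a term of every fit. Eggs of each population were soaked in separate dishes, but nothing says that arrays of 1 population came from separate cultures, so p-values of the exposure comparisons measure the spread between these RNA samples.

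Probe sets were named through the platform annotation and updated through the gene identifiers of a RefSeq gene table. Of 18769 probe sets, 13647 list 1 gene, 402 several and 4720 are unlisted and so unnamed here; 13544 were named through the RefSeq table. A probe set was tested if its value was at least 4 on at least 5 arrays, which left 9729, of which 8595 name 1 of 8051 genes. No coordinates are given because the build behind the annotation is not given in the sources used here.

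The analysis used R 4.3.3 and limma 3.58.1. For exposure and for pairs of populations, limma fitted the means of the 12 combinations of population and exposure plus the day to all 34 arrays, which share the estimate of spread. For selection, the mean of the water and ethanol coefficients of each population was taken as 1 replicate, giving 6 values and 2 populations per regime, and for the interactions the ethanol-minus-water difference of each population. Tests were two-sided, with an intensity trend in eBayes and Benjamini-Hochberg adjustment over the 9729 probe sets at 0.05. Errors given as ± are limma standard errors unless SD is stated. For the comparison of the response with the difference between regimes, r and the share of equal signs are given without a p-value, and values without any effect were simulated 50 times from the residual spread.

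All 28 gene lists, the main comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 largest increases and 10 largest decreases of the exposure comparison with 1 sign in all 6 populations; for ethanol against control populations the same or, failing that, the 20 smallest p-values with both populations of a regime on the same side; for other comparisons the 5 largest in each direction or the 5 smallest p-values; Adh, Adhr, Aldh and AcCoAS throughout; and up to 4 members per list with the smallest p. A gene is represented by its probe set with the highest mean. Lists of at least 5 tested genes, 26 in number, were tested with the camera test of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data.

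The tests were tested on simulated data with the measured means, residual spread and spread between populations and 50 changed probe sets of each of 4 sizes. For exposure over all populations, 50.0% of changes of 0.25, 90.0% of changes of 0.5 and 100% of changes of 1 on the log2 scale were recovered, and 5.56% of calls were false. For the ethanol against control populations, 4.0%, 36.0%, 72.0% and 96.0% of changes of 0.25, 0.5, 1 and 2 were recovered. For the interaction of the same regimes, 0%, 12.0%, 60.0% and 96.0% were recovered. Populations were drawn independently in these data, and with fewer changed probe sets the adjusted threshold would be stricter.

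The alternatives were no filter, a filter on a mean of at least 6, no day term, centring on array medians, quantile normalization, no trend, robust moderation, 1 probe set per gene, each day, population or array left out, arrays as replicates, population as a random block, 1 exposure alone, population differences as replicates for exposure, and the list settings above. Alternatives chosen after seeing the data were each extraction day fitted alone, the population number as a block, the labels of the variable and ethanol populations of the same number interchanged on day 5, the pairs of M1 with E1 and M2 with E2 under the alternatives, the ethanol and variable populations together against the control populations, and a list of pentose phosphate genes.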

Results

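The series holds whole-larva expression profiles from a long-running selection experiment in Drosophila melanogaster. From 1 outbred base population, 6 laboratory populations were kept for more than 300 generations on standard medium (control regime, populations R1 and R2), on medium with 12% ethanol (ethanol regime, E1 and E2) or on a mixture of vials of both kinds in each generation (variable regime, M1 and M2). Eggs from all populations, after rearing on standard medium, lay for 15 hours under distilled water or under an 18% ethanol solution that came to about 12% once mixed with the laying medium, and newly hatched first-instar larvae were then collected. Each array holds RNA pooled from a group of larvae, extracted on 1 of 3 days that the titles number 1, 2 and 5. The 34 arrays analysed here comprise 6 each for water- and ethanol-exposed control larvae, 6 each for the ethanol regime and 5 each for the variable regime, so 17 arrays per exposure. The variable regime has no array of ethanol-exposed M2 on day 1 or of water-exposed M1 on day 2. The deposited values are log2 expression, with array medians between 3.89 and 4.02 and between 9273 and 9400 of 18769 probe sets at a value of 4 or more. Correlations between arrays ran from 0.984 to 0.998, and no pair of arrays held identical values. The number of arrays, and for the regimes the number of populations, limits the precision.

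The first comparison asks which transcripts differ between larvae that hatched from ethanol-soaked and water-soaked eggs, averaged over the 6 populations. The 10 largest decreases after ethanol included genes for enzymes that break down lipid or carbohydrate, while others of that kind, such as Mal-A8 and Lip1, rose. Lip3, which encodes a lipase, fell by 5.20 ± 0.42 on the log2 scale (standard error), from 8.54 ± 1.60 (SD, n = 17) in water to 3.44 ± 1.64 (SD, n = 17) in ethanol, a 36.9-fold difference with limma adjusted p = 5.88e-10. LManIII, an alpha-mannosidase gene, fell by 4.45 ± 0.45, the amylase-related gene Amyrel fell by 3.69 ± 0.30 and the maltase gene Mal-A4 fell by 3.26 ± 0.28. The immune peptide gene BomS6 fell by 3.12 ± 0.26, and CG6283, CG12951, CG4362, CG8093 and CG14219 fell by 5.02 ± 0.28, 4.67 ± 0.38, 4.26 ± 0.25, 3.66 ± 0.30 and 3.01 ± 0.20. In ethanol the mean value of Lip3 lay below the detection level of 4 set for the test, as did those of CG12951, LManIII, CG4362 and Amyrel, so the size of these decreases depends on the background correction.

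Among transcripts that rose, CG13215 went from 4.69 ± 0.67 to 8.21 ± 0.40 (SD, n = 17 each), a log2 change of 3.50 ± 0.14 or 11.3-fold, with limma adjusted p = 1.52e-15. CG12766 rose by 3.31 ± 0.20, the salivary glue gene Sgs5 by 2.74 ± 0.24 from a mean of 3.41 in water, below that level, CG1774 by 2.59 ± 0.25 and Mal-A8, a second maltase gene, by 2.58 ± 0.17. Prat2, an amidotransferase gene of purine synthesis, rose by 2.38 ± 0.33, CG32444 by 2.35 ± 0.09, the odorant-binding protein gene Obp99d by 2.10 ± 0.11, CG14205 by 2.09 ± 0.25 and CG12826 by 1.98 ± 0.11. Each of these 20 genes moved the same way in 6 of 6 populations, which the rule that named them required. AcCoAS, the enzyme that turns acetate into acetyl-CoA, rose by 0.99 ± 0.05, a 1.99-fold change with limma adjusted p = 4.16e-13. The alcohol dehydrogenase gene Adh is read here only by 2 probe sets that list both Adh and Adhr. Both rose, the one with a mean of 7.40 in water by 0.63 ± 0.08 and the one with a mean of 13.7 by 0.17 ± 0.02. These increases cannot be assigned to either gene, and no tested probe set named Aldh. The probe set at 13.7 lay near the top of the scale. On the ethanol-exposed M1 array of day 1 its 13.99 was the highest value of the array. Its changes here and below may therefore be limited by that ceiling.

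**Figure D1:**
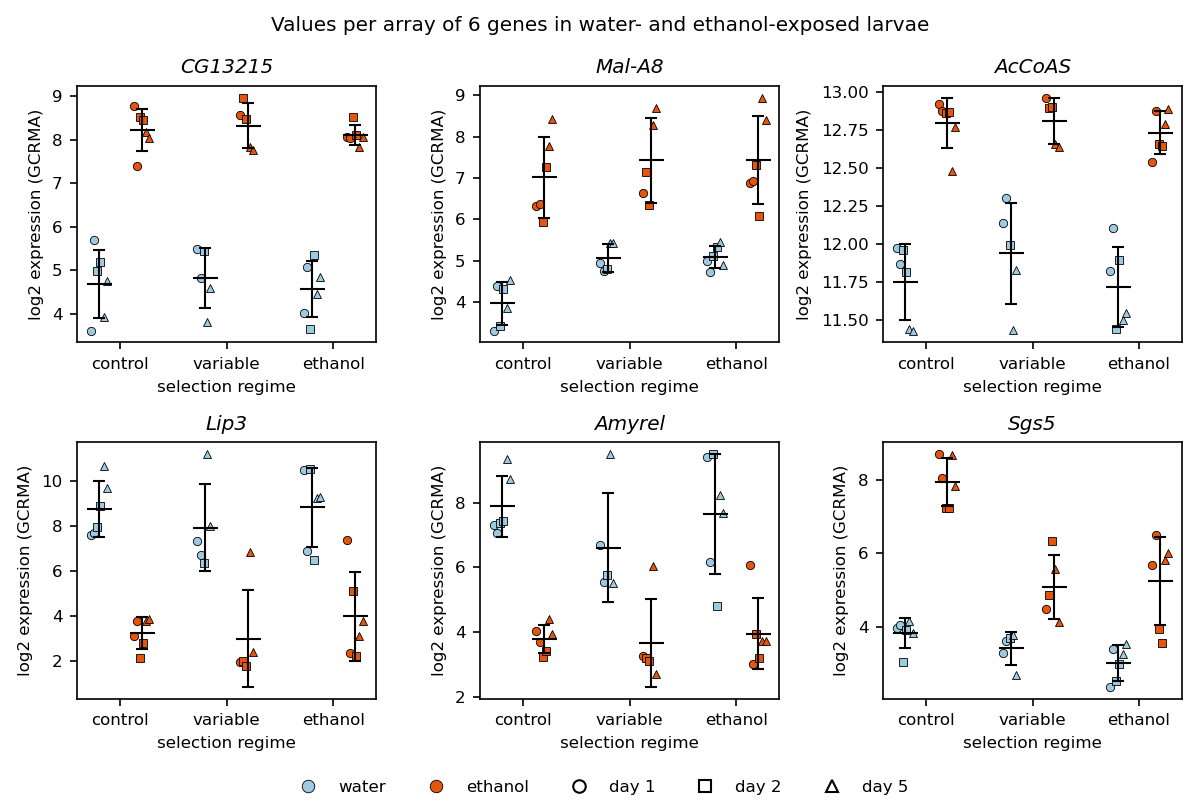
Log2 expression on each array (GCRMA values, vertical axis) for 6 genes by selection regime (horizontal axis), with blue points for water and orange points for ethanol, marker shape for the extraction day, and bars for the mean ± SD of 5 or 6 arrays. CG13215 lay at 4.69 in water and 8.21 in ethanol on average, and Lip3 at 8.54 and 3.44.

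Over all 9729 probe sets tested, limma called 3037 (31.2%) at an adjusted p under 0.05, 1476 higher and 1561 lower in ethanol, and 139 of these changed more than 2-fold. Of the 3037, 2331 had the same sign in all 6 populations. The median size of the change among the calls was 0.27 on the log2 scale. Fitted within 1 extraction day at a time, a choice made after seeing the data, the change of Lip3 was -4.30 ± 0.26, -5.24 ± 0.24 and -5.73 ± 0.24 on days 1, 2 and 5. That of CG13215 was 3.40 ± 0.40, 3.49 ± 0.24 and 3.56 ± 0.16, and that of AcCoAS was 0.85 ± 0.05, 0.96 ± 0.06 and 1.17 ± 0.07. CG14205 did not pass on day 1 (1.01 ± 0.54, limma adjusted p = 0.293), nor did the Adh and Adhr probe set at 7.40 (0.53 ± 0.16, limma adjusted p = 0.081). Within days 1, 2 and 5 limma called 627, 2047 and 1299 probe sets, and 2914 of the 3037 had the same sign on all 3 days. Without the arrays of day 2 the count was 1797.

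Glycolysis genes rose as a group: 10 of 12 tested members were higher, none was lower, and 10 passed when adjusted over the list alone. Ald1 (aldolase) rose by 0.36 ± 0.03, Eno (enolase) by 0.22 ± 0.02, fbp (fructose-bisphosphatase, an enzyme of the reverse pathway) by 0.31 ± 0.03 and Pgi (phosphoglucose isomerase) by 0.45 ± 0.05. The limma camera test gave adjusted p = 5.18e-07 for this list and adjusted p = 0.00252 with an estimated correlation. The list of ethanol and acetaldehyde metabolism has 16 genes, of which 9 were tested, without Adh, Adhr and Aldh. Of these 9 members 6 were higher and 2 lower, with the same counts when adjusted over the list alone. AcCoAS led it, followed by Gpdh1 (glycerol-3-phosphate dehydrogenase, 0.42 ± 0.04), Mdh1 (malate dehydrogenase, 0.32 ± 0.03) and Men (malic enzyme, 0.44 ± 0.05), with camera adjusted p = 0.00734 and adjusted p = 0.0457 with an estimated correlation. These were the 2 lists whose call held with an estimated correlation.

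Of 18 tested genes of fatty acid and lipid synthesis and storage, 10 were higher, 2 lower and 6 did not pass; adjusted over the list alone, 10 were higher and 3 lower. ACC, the acetyl-CoA carboxylase that commits acetyl-CoA to fatty acid synthesis, rose by 1.06 ± 0.05, the fatty acid synthase genes FASN1 and FASN2 by 0.73 ± 0.05 and 0.75 ± 0.10, and the lipid droplet gene Lsd-1 by 0.96 ± 0.10. Camera gave adjusted p = 0.000996 for an increase, lost at adjusted p = 0.116 with an estimated correlation. In the lipolysis and fatty acid oxidation list, 6 of 15 members were lower and 1 higher, with the same counts when adjusted over the list alone. Besides Lip3, Lip4 fell by 1.08 ± 0.09 and yip2, a thiolase gene, fell by 0.32 ± 0.06. Lip1 rose by 0.70 ± 0.11. The camera adjusted p = 0.0378 became adjusted p = 0.418 with an estimated correlation. This call was also lost with a filter on a mean of at least 6 (adjusted p = 0.0598), without day 1 (adjusted p = 0.0546), day 2 (adjusted p = 0.121), M1 (adjusted p = 0.0719) or E2 (adjusted p = 0.0696), and within day 5 alone (adjusted p = 0.075).

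Digestive peptidases and carbohydrases went both ways, with 19 of 38 lower, 4 higher and 15 not passing, and 20 lower and 5 higher when adjusted over the list alone. Amyrel fell as given above, whereas the maltase genes Mal-A8, Mal-B1 and Mal-A6 rose by 2.58 ± 0.17, 1.83 ± 0.13 and 1.70 ± 0.14. Camera gave adjusted p = 0.000128 for a decrease, lost at adjusted p = 0.49 with an estimated correlation. In the list of cell cycle and DNA replication, 9 of 12 members were lower and 1 higher, also when adjusted over the list alone. RnrL, the large subunit of ribonucleotide reductase, fell by 0.82 ± 0.09, the replication clamp gene PCNA fell by 0.60 ± 0.07, and the replicative helicase genes Mcm5 and dpa fell by 0.60 ± 0.07 and 0.47 ± 0.07. The camera adjusted p = 3e-04 became adjusted p = 0.185 with an estimated correlation, and within day 1 alone it was adjusted p = 0.068.

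**Figure D2:**
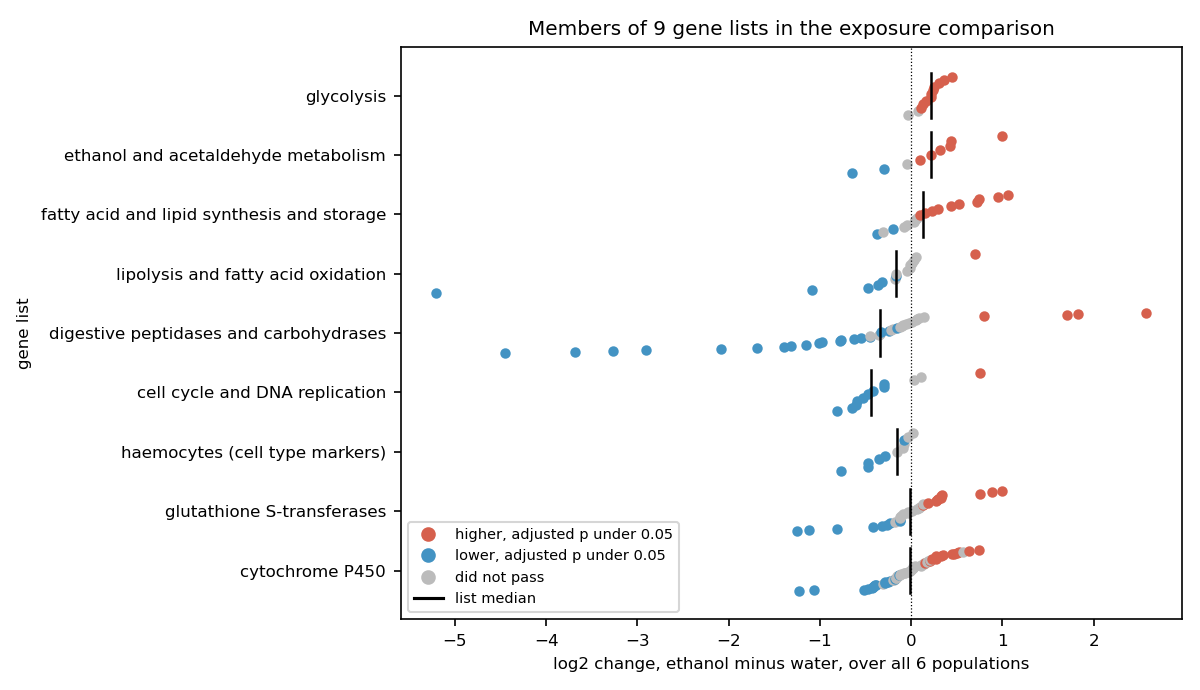
Log2 change of ethanol against water over all 6 populations (horizontal axis) for each tested member of 9 gene lists (vertical axis); red and blue points passed the test as higher and lower, grey points did not, and black bars are list medians. In glycolysis 10 of 12 members were higher, and in cell cycle and DNA replication 9 of 12 were lower.

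Gene families of detoxification and stress moved in both directions, and over all days no list of this kind was called. Of 32 glutathione S-transferase genes 11 were higher and 9 lower (11 and 10 adjusted over the list alone), with GstE9 rising by 0.99 ± 0.11 and GstD10 falling by 1.12 ± 0.13, and camera gave adjusted p = 0.781. Of 59 cytochrome P450 genes 15 were higher and 16 lower (18 and 18 adjusted over the list alone; camera adjusted p = 0.781), with Cyp6a18 falling by 1.23 ± 0.12 and Cyp4c3 rising by 0.74 ± 0.09. Of 27 UDP-glycosyltransferase genes 9 were higher and 2 lower (9 and 4 adjusted over the list alone), led by Ugt36D1 with a rise of 0.84 ± 0.08, at camera adjusted p = 0.293. Within day 5 alone this list was called as higher (camera adjusted p = 0.0203). Heat shock and chaperone genes numbered 4 higher and 3 lower of 15 (5 and 3 adjusted over the list alone), and Hsc70-3 fell by 0.25 ± 0.04 while stv rose by 0.23 ± 0.04, at camera adjusted p = 0.781. Oxidative stress genes numbered 2 higher and 2 lower of 14, also adjusted over the list alone, among them the catalase gene Cat, which fell by 0.65 ± 0.08, at camera adjusted p = 0.873. Of 11 immune genes 1 was higher and 3 were lower, also adjusted over the list alone, and PGRP-SC2, an amidase gene of peptidoglycan recognition, fell by 1.52 ± 0.15 at camera adjusted p = 0.446.

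In the FOXO and starvation list 6 of 14 genes were higher and 3 lower, also adjusted over the list alone. The sugar-responsive transcription factor gene sug rose by 1.97 ± 0.18, Sesn by 0.48 ± 0.05 and the adipokinetic hormone receptor gene AkhR by 0.63 ± 0.07, and camera gave adjusted p = 0.597. Of 15 ecdysone and moulting genes 1 was higher and 3 lower, also adjusted over the list alone, and Cyp18a1, which inactivates ecdysteroids, fell by 0.95 ± 0.10 at camera adjusted p = 0.768. Cuticle protein genes numbered 10 higher and 8 lower of 63 (8 and 8 adjusted over the list alone; camera adjusted p = 0.898). Cytosolic ribosomal protein genes numbered 0 higher and 3 lower of 32 (0 and 0 adjusted over the list alone; camera adjusted p = 0.253). Of 58 oxidative phosphorylation genes 4 were higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.297). Of 69 mitochondrial ribosomal protein genes 3 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.898), but within day 1 alone the list was called as lower (adjusted p = 0.0455). Of 20 alcohol behaviour genes 2 were higher, NPFR by 0.19 ± 0.07 and rut by 0.24 ± 0.09, and 0 passed adjusted over the list alone at camera adjusted p = 0.388. The median, mean and test direction differed in sign for the glutathione S-transferase, oxidative stress, cuticle, mitochondrial ribosomal, FOXO, ecdysone, fat body, salivary gland and embryonic patterning lists, none of which was called.

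Among cell type markers, 6 of 11 haemocyte genes were lower and none was higher, also adjusted over the list alone. NimC1 fell by 0.77 ± 0.11, Pxn by 0.48 ± 0.11, Hml by 0.47 ± 0.11 and crq by 0.35 ± 0.08, with camera adjusted p = 0.00985 and adjusted p = 0.185 with an estimated correlation. This call was also lost without day 1 (adjusted p = 0.101), and within day 5 alone the list had adjusted p = 0.371. Neuron and muscle markers each had 1 of 12 lower and none higher, also adjusted over the list alone, brp at -0.29 ± 0.08 and TpnC41C at -0.35 ± 0.09, with camera adjusted p = 0.781 and 0.701. Within day 5 alone the muscle list was called as lower (adjusted p = 0.0315). Of 5 fat body markers 1 was higher, Gbs-70E by 1.49 ± 0.13, and 1 lower (camera adjusted p = 0.793). Of 10 tracheal and epidermal markers 2 were higher, the chitin deacetylase genes serp by 0.40 ± 0.10 and verm by 0.39 ± 0.12 (camera adjusted p = 0.388). Within day 1 alone this list was called as higher (adjusted p = 0.0455). Salivary gland and midgut markers numbered 2 higher and 2 lower of 10 (camera adjusted p = 0.781), and embryonic patterning genes 3 higher and 1 lower of 9, with hh falling by 1.05 ± 0.12 (camera adjusted p = 0.631). In these 4 lists the counts were the same adjusted over the list alone. Of 4 tested male germ line genes mia rose by 0.65 ± 0.07, also adjusted over the list alone, and of the ovary and egg shell list no member reached the detection level.

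The same question was put within each regime, and the leading genes overlapped: Lip3, CG6283, LManIII and CG12951 were among the 5 largest decreases of every regime. In control larvae Sgs5 rose by 4.13 ± 0.40, CG12766 by 3.92 ± 0.33 and Prat2 by 3.88 ± 0.55, while Lip3 changed by -5.51 ± 0.70, CG6283 by -5.26 ± 0.47 and LManIII by -5.19 ± 0.74. In variable larvae CG13215 rose by 3.43 ± 0.27 and CG12766 by 3.18 ± 0.38, while Lip3 changed by -5.26 ± 0.79 and CG6283 by -4.72 ± 0.53. In ethanol-regime larvae CG13215 rose by 3.54 ± 0.23 and CG1774 by 2.85 ± 0.41, while CG6283 changed by -5.08 ± 0.47 and CG12951 by -4.87 ± 0.62. AcCoAS rose by 1.04 ± 0.09, 0.92 ± 0.10 and 1.01 ± 0.09 in the control, variable and ethanol regimes. The Adh and Adhr probe set at 7.40 rose by 0.60 ± 0.13, 0.73 ± 0.15 and 0.55 ± 0.13.

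Within the control regime limma called 1759 probe sets, 774 higher and 985 lower, within the variable regime 665, 340 higher and 325 lower, and within the ethanol regime 820, 443 higher and 377 lower. The control and variable regimes shared 561 calls, the control and ethanol regimes 644, and the variable and ethanol regimes 465, against 120, 148 and 56.0 for independent lists. All 3 regimes shared 430 calls, and every shared call had the same sign. On days 1, 2 and 5 alone limma called 50, 981 and 779 probe sets in the control regime, 8, 108 and 457 in the variable regime and 17, 419 and 289 in the ethanol regime. The variable response rests on M1 alone on day 1 and on M2 alone on day 2, where an array is missing. The fit without the replicate block of extraction day called 1029, 335 and 404 in the control, variable and ethanol regimes. Without day 1 the counts were 1061, 418 and 474, without day 2 they were 725, 183 and 244, and without day 5 the variable regime had 411. With the day 5 labels of the variable and ethanol populations of the same number interchanged, a choice made after seeing the data, the variable regime had 1220 and the ethanol regime 1189. They were 733 without R1 and 655 without R2 in the control regime, 209 without M1 and 169 without M2 in the variable regime, and 316 without E1 and 276 without E2 in the ethanol regime. Without the day 5 array of water-exposed M1 or of ethanol-exposed M2, the variable regime had 382 or 372. CG12951 and LManIII no longer passed in the variable regime without M1 (limma adjusted p = 0.0541 and 0.146), and without day 2 LManIII did not pass in the variable or the ethanol regime (limma adjusted p = 0.0944 and 0.0513). The Adh and Adhr probe set at 7.40 did not pass in the control regime without day 5 or R1 (limma adjusted p = 0.0784 and 0.0763) or in the variable regime without day 5, M1 or M2 (0.0977, 0.115 and 0.0716). It also did not pass in the ethanol regime without day 1, day 2, E1 or E2 (0.0928, 0.0603, 0.0936 and 0.226).

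The selection comparison asks which transcripts differ between populations with and without a history of ethanol, with the population as the replicate. No gene passed. Against the control populations, the ethanol populations had lower Sgs5, with means over both exposures of 4.14 and 4.55 in E1 and E2 and 6.18 and 6.04 in R1 and R2, a difference of -1.77 ± 0.17 that did not pass at limma adjusted p = 0.342. In water-exposed larvae alone the difference was -0.82 ± 0.22, with the means of both regimes below the detection level of 4. CG13325 differed by -1.77 ± 0.23, Lime by -1.29 ± 0.18, CG33459 by -1.16 ± 0.17 and the alkaline phosphatase gene Alp8 by 1.29 ± 0.18. The Alp8 difference lay mostly in ethanol-exposed larvae. Its ethanol-minus-water change was -3.89 and -2.69 in R1 and R2 and -1.43 and -1.25 in E1 and E2. The means of CG33459 in E1 and E2 (3.31 and 3.15) lay below the detection level of 4, so the size of its difference depends on the background correction. Smaller differences were those of CG9147 (0.74 ± 0.10), the cuticle protein genes Cpr65Ec (0.67 ± 0.07) and Cpr67B (-0.55 ± 0.07), the glutaminyl cyclase gene QC (0.63 ± 0.08), the splicing factor gene Phf5a (0.52 ± 0.06) and the juvenile hormone-inducible gene JhI-26 (-0.37 ± 0.04). CG14408 differed by -0.67 ± 0.06 on 1 probe set and by -0.13 and 0.02 on its others, and CG30109 by 0.48 ± 0.07 and 0.14 on its 2 probe sets. The remaining genes with the smallest p were CG6733 (0.53), CG13862 (0.59), CG5323 (0.32), CG11562 (0.49), CG3106 (-0.40), CG6610 (0.43) and CG10560 (-0.44). The adjusted p of all 20 lay between 0.342 and 0.346. AcCoAS differed by -0.05 ± 0.08, and the Adh and Adhr probe sets by 0.15 ± 0.10 for the one at 7.40 and 0.07 ± 0.03 for the one at 13.7, none of them passing.

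Limma called 0 of 9729 probe sets between the ethanol and control populations, with 920 at an unadjusted p under 0.05 against 486 by chance. Between the variable and control populations it called 0, with 722 at an unadjusted p under 0.05. Of these CG14408 (-0.75 ± 0.06), Phf5a (0.56 ± 0.06), Sgs5 (-1.65 ± 0.17), CG6733 (0.56 ± 0.06) and CG13862 (0.67 ± 0.08) had the smallest p, all at limma adjusted p = 0.384. Between the ethanol and variable populations it called 0, with 124 at an unadjusted p under 0.05, below the 486 of chance. The spread of this test holds the M1 minus M2 and E1 minus E2 differences. These were largely shared (r = 0.817) and so cancel between the regimes, which makes the test insensitive. The 0 calls therefore do not show that the regimes are alike. The genes with the smallest p, csw (-0.23 ± 0.06), Nadk2 (0.23 ± 0.06), the adipokinetic hormone gene Akh (0.26 ± 0.07), tum (-0.34 ± 0.09) and TwdlN (0.11 ± 0.03), did not pass. Taking every array as a replicate and ignoring populations, limma called 767 probe sets for ethanol against control and 418 for variable against control, and with population as a random block 156 and 81. Without day 5 or without E2 the count for ethanol against control was 1. Within each day alone all 3 limma counts were 0, with a single variable population on days 1 and 2. On days 1, 2 and 5 there were 371, 693 and 388 probe sets at an unadjusted p under 0.05 for ethanol against control, 218, 226 and 573 for variable against control and 129, 126 and 175 for ethanol against variable. In data simulated with the measured spread between populations, the population-level test of ethanol against control recovered 72.0% of probe sets changed by 1 on the log2 scale. It recovered 36.0% of those changed by 0.5. Populations were drawn independently there, unlike the measured ones. Many probe sets were changed together, and with fewer the adjusted threshold would be stricter. These shares therefore do not show how many differences of such sizes the 0 calls could have missed.

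By the camera test, 4 lists shifted between the ethanol and control populations, and none of these calls held with an estimated correlation. Mitochondrial ribosomal protein genes had positive differences in 60 of 69 members (median 0.07, adjusted p = 4.37e-07; adjusted p = 0.536 with an estimated correlation), with mRpL18 at 0.43 ± 0.09. The list was called within days 1 and 5 alone but not within day 2 (adjusted p = 0.0894). All 12 cell cycle and DNA replication genes had positive differences (median 0.27, adjusted p = 8.6e-05; adjusted p = 0.536 with an estimated correlation), with Mcm2 at 0.66 ± 0.11 and RnrL at 0.51 ± 0.10, and 3 passed when adjusted over the list alone. In water-exposed larvae alone the cell cycle list was not called (adjusted p = 0.435), nor was it within day 2 (adjusted p = 0.0543). Neuron markers had a median of -0.09 (adjusted p = 0.017; adjusted p = 0.536 with an estimated correlation) and digestive genes of -0.09 (adjusted p = 0.0361; adjusted p = 0.846 with an estimated correlation). The neuron call was lost without day 1 (adjusted p = 0.181), day 5 (adjusted p = 0.203), R2 (adjusted p = 0.0703) or E1 (adjusted p = 0.0638), in ethanol-exposed larvae alone (adjusted p = 0.0511) and within day 2 (adjusted p = 0.886). The digestive call was lost without day 2 (adjusted p = 0.234), day 5 (adjusted p = 0.0941), R1 (adjusted p = 0.637) or E2 (adjusted p = 0.827). It was also lost without the intensity trend (adjusted p = 0.0742), in ethanol-exposed larvae alone (adjusted p = 0.133) and within day 1 (adjusted p = 0.953). Both were lost with population as a random block, at adjusted p = 0.0532. Other lists were called under an alternative. Salivary gland and midgut markers (lower) were called with population number as a block, chosen after seeing the data (adjusted p = 0.0372), with arrays as replicates (0.0487), with population as a random block (0.04) and without day 1 (0.00376), R2 (0.0458) or E1 (0.0405). Cytochrome P450 genes (lower) were called with number as a block (adjusted p = 0.0372), in ethanol-exposed larvae (0.0431) and without E1 (0.0296). Ethanol metabolism and lipolysis genes (higher) were called in water-exposed larvae (adjusted p = 0.0221 and 0.0375) and without E2 (0.0478 and 0.0142), and ethanol metabolism also over all probe sets of its genes (0.00952). Oxidative stress genes were called without R2 (adjusted p = 0.015), glutathione S-transferases and muscle markers without E1 (0.0109 and 0.0233) and lipid synthesis without E2 (0.046), all as lower. Within day 2 alone lipid synthesis and salivary gland markers were called as lower (adjusted p = 0.0385 and 0.0219). Within day 5 alone ethanol metabolism and cytosolic ribosomal genes were called as higher (adjusted p = 0.049 and 0.0277) and cytochrome P450 genes as lower (0.049). The median, mean and test direction differed in sign for the immune, UDP-glycosyltransferase, FOXO, cytosolic ribosomal and tracheal lists, none of which was called. No member of any list passed over all probe sets. Adjusted over the list alone, members passed also in ethanol metabolism (1 higher, Gpdh1 at 0.32 ± 0.05), heat shock genes (1 higher, Hsp60A at 0.29 ± 0.05), cuticle proteins (2 higher and 1 lower) and the salivary gland and midgut list (2 lower, Sgs5 and Vha100-4 at -0.43 ± 0.11).

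The interaction comparison asks whether the response to ethanol differs between regimes, on the ethanol-minus-water difference of each population. The response of Sgs5 was 4.49 and 3.78 in R1 and R2 against 2.43 and 2.05 in E1 and E2 and 1.65 and 2.02 in M1 and M2. The difference was -1.89 ± 0.27 for ethanol against control (limma adjusted p = 0.117) and -2.30 ± 0.27 for variable against control (limma adjusted p = 0.0723), and neither passed. The means of Sgs5 in water, 3.83, 3.41 and 3.01 in the control, variable and ethanol regimes, all lay below the detection level of 4, so its responses depend on the background correction; in ethanol they were 7.96, 5.08 and 5.25. For ethanol against control, Mal-A6 (-1.25 ± 0.17), the lipase gene mag (-1.15 ± 0.18), the alkaline phosphatase gene phu (2.09 ± 0.32) and CG16775 (1.07 ± 0.17) also missed at limma adjusted p = 0.117. For variable against control, the next were Npc2e (0.82 ± 0.12), Alp8 (2.12 ± 0.31), CG14219 (1.51 ± 0.25) and CG8093 (1.27 ± 0.22). For ethanol against variable they were mag (-1.14 ± 0.18), CG18088 (0.78 ± 0.21), RpS7 (-0.24 ± 0.07), CG8888 (0.48 ± 0.14) and Uxt (-0.62 ± 0.18), none passing. AcCoAS responses differed by -0.03 ± 0.09 between ethanol and control populations. Limma called 0 probe sets in each of the 3 interactions, with 394, 529 and 211 at an unadjusted p under 0.05 for ethanol against control, variable against control and ethanol against variable. Chance would give 486. Leaving out R1 gave 5 and 19 calls for ethanol and variable against control, and leaving out R2 gave 20 and 18; the single control population is then assumed to vary like the others. For ethanol against control, 10 probe sets were called without the day 1 array of ethanol-exposed R2, among them Sgs5, Mal-A6 and mag, and 1 was called, phu, without M1, M2, day 5 or the day 5 array of water-exposed M1. For variable against control, 6 were called without M2 and 4 without the day 1 array of ethanol-exposed R2. In the same comparison 2 were called without day 2, without the day 1 or the day 2 array of water-exposed R2, or without the day 5 array of water-exposed R1. The count was 1 without the day 1 array of ethanol-exposed R1 or water-exposed E1, the day 2 array of ethanol-exposed R2, or the day 5 array of ethanol-exposed E1 or water-exposed M2. Sgs5 passed there without day 2 (limma adjusted p = 0.00445), with robust moderation (limma adjusted p = 0.0136) and without the replicate block (limma adjusted p = 0.0435). With population number as a block, chosen after seeing the data, 4 probe sets passed in that comparison, among them Sgs5 and Alp8 (limma adjusted p = 0.0175 for both). For ethanol against variable, mag passed without the day 5 array of ethanol-exposed M1 (limma adjusted p = 0.0325). Within days 1, 2 and 5 alone limma called 0, 1 and 0 probe sets for ethanol against control (473, 844 and 926 at an unadjusted p under 0.05), 0, 0 and 5 for variable against control (126, 405 and 438) and 0, 0 and 1 for ethanol against variable (265, 559 and 1192), with a single variable population on days 1 and 2.

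As a group, cell cycle and DNA replication genes had a median response of -0.62 and -0.77 in R1 and R2, -0.35 and -0.23 in E1 and E2 and -0.17 and -0.58 in M1 and M2. For ethanol against control, 11 of the 12 differences were positive, with RnrL at 0.70 ± 0.17 and PCNA at 0.49 ± 0.14, 2 passed when adjusted over the list alone, and the camera adjusted p = 1.2e-06 became adjusted p = 0.35 with an estimated correlation. Camera also called mitochondrial ribosomal genes as positive (adjusted p = 0.000367) and FOXO genes (adjusted p = 0.00105), ethanol metabolism (adjusted p = 0.00147), cytochrome P450 genes (adjusted p = 0.00673), immune genes (adjusted p = 0.0108), glycolysis (adjusted p = 0.0113) and lipolysis (adjusted p = 0.0416) as negative. With an estimated correlation none of these held, at adjusted p = 0.35 for mitochondrial ribosomal, FOXO, ethanol metabolism and immune genes, adjusted p = 0.354 for P450 genes and adjusted p = 0.566 for glycolysis and lipolysis. As for selection, that setting rests on 6 population values, so its failure alone does not decide against a list. Without day 1 the mitochondrial ribosomal list turned negative (adjusted p = 0.684), and it was not called without R2 (adjusted p = 0.11) or E1 (adjusted p = 0.109). FOXO genes were not called without day 2 or R2 (adjusted p = 0.0523 for both), nor P450 genes without day 1 (adjusted p = 0.0993) or E1 (adjusted p = 0.198). Immune genes were not called without day 5 (adjusted p = 0.759) or R1 (adjusted p = 0.105), with no filter (adjusted p = 0.243) or with a filter on a mean of at least 6 (adjusted p = 0.217). Glycolysis was not called without day 2 (adjusted p = 0.199), R2 (adjusted p = 0.11) or E1 (adjusted p = 0.178). Lipolysis was not called without day 1 (adjusted p = 0.256), day 2 (adjusted p = 0.176), R2 (adjusted p = 0.519) or E1 (adjusted p = 0.256), and without the intensity trend both had adjusted p = 0.0817. Lipolysis was also not called with no filter (adjusted p = 0.0685) or with arrays as replicates (adjusted p = 0.0503). Within day 5 alone neither the cell cycle list (adjusted p = 0.0675) nor the mitochondrial ribosomal list (negative, adjusted p = 0.512) was called, and within day 2 the latter had adjusted p = 0.243. Ethanol metabolism was called within day 1 but not days 2 and 5 (adjusted p = 0.118 and 0.512), as were P450 genes (0.173 and 0.678) and lipolysis (0.173 and 0.963). Glycolysis was called within day 2 but not days 1 and 5 (adjusted p = 0.181 and 0.678), immune genes within day 5 but not days 1 and 2 (0.801, with a positive shift, and 0.389), and FOXO genes within days 1 and 2 but not day 5 (0.678). Other lists were called under an alternative. Salivary gland and midgut markers (lower) were called with population number as a block (adjusted p = 0.0246) and without R2 (0.0182) or E1 (0.025). UDP-glycosyltransferases (lower) were called with the filter on a mean of at least 6 (adjusted p = 0.0179) and without day 1 (0.0416) or R2 (0.00551), and ecdysone genes (lower) with that filter (0.0204), over all probe sets of the list genes (0.0301) and without day 5 (0.0037). Cuticle genes were called without day 1 (adjusted p = 0.00012), glutathione S-transferases without R2 or E2 (0.00253 and 0.0396), heat shock genes without R2 (0.0252) and embryonic patterning genes with that filter (0.0424), all as lower, and digestive genes as higher without R1 (0.00301). Within day 1 alone oxidative phosphorylation genes were called as higher (adjusted p = 0.00133) and ecdysone genes as lower (0.0147). UDP-glycosyltransferases and muscle markers were called as lower within day 2 (adjusted p = 0.0365 and 0.000748), and cuticle genes within day 5 (0.00267). The median, mean and test direction differed in sign for the neuron, muscle and haemocyte lists, none of which was called. Adjusted over the list alone, 1 immune gene was higher and 2 lower, 1 digestive gene was higher and 4 lower, and Sgs5 was lower in the salivary gland list.

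**Figure D3:**
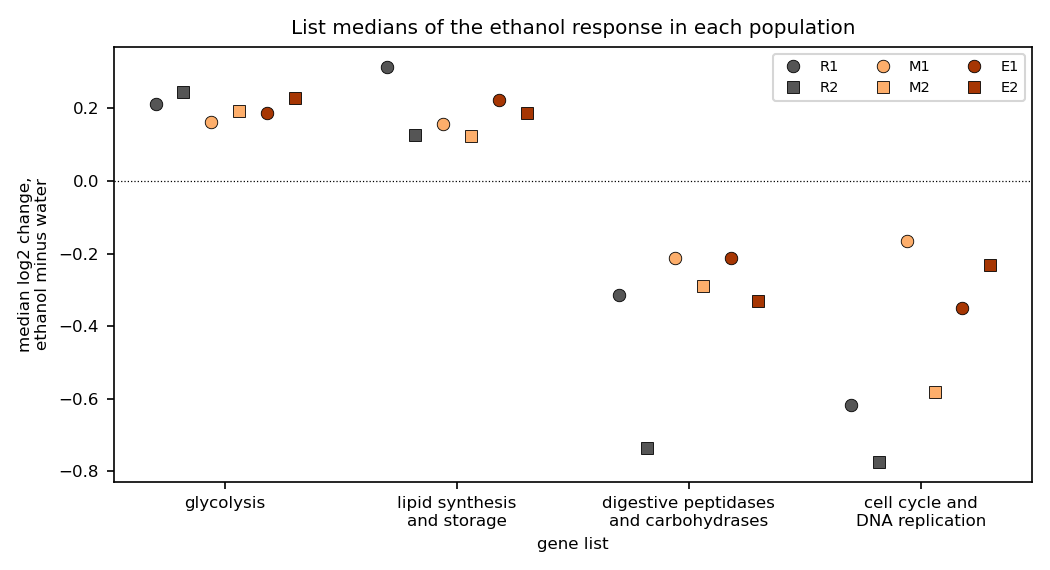
Median log2 change of ethanol against water (vertical axis) over the members of 4 gene lists (horizontal axis) in each of the 6 populations, with grey, light orange and dark orange points for the control, variable and ethanol regimes, circles for populations numbered 1 and squares for those numbered 2. Cell cycle and DNA replication genes had medians of -0.62 and -0.77 in R1 and R2 and of -0.35 and -0.23 in E1 and E2.

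Populations kept under the same regime also differed. R1 had higher levels than R2 of the cytochrome P450 gene Cyp12d1-d, by 5.89 ± 0.92, and of the alpha-mannosidase gene LManV, by 2.80 ± 0.44. The carbonic anhydrase gene CAH6 was lower in R1, at -3.11 ± 0.27, as was the lipocalin gene NLaz, at -2.35 ± 0.21. CG43117 was higher in M1 than in M2 by 3.18 ± 0.21 and CG11034 by 2.60 ± 0.38, and CG32751 was lower, at -2.67 ± 0.54. LManIII was higher in E1 than in E2 by 3.46 ± 0.74, LManV by 3.12 ± 0.44 and CG8093 by 3.02 ± 0.49, and Cyp12d1-d was lower, at -4.36 ± 0.92, as was the zinc transporter gene Zip102B, at -3.43 ± 0.37. CG43117 was also higher in E1 than in E2, and CG32751 lower, by 3.33 ± 0.47. AcCoAS did not pass in any of the 3 pairs, but it passed between E1 and E2 without day 5 (limma adjusted p = 0.0189) or without the day 5 array of ethanol-exposed E1 (limma adjusted p = 0.0279). With the day 5 labels of the variable and ethanol populations of the same number interchanged, chosen after seeing the data, it was at -0.24 and passed (limma adjusted p = 0.0356).

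By the camera test, digestive peptidases and carbohydrases were shifted upward in population 1 against population 2 of every regime. Of 38 members, 6 were higher and 0 lower in R1 than in R2 (8 and 2 adjusted over the list alone; adjusted p = 0.0351). In M1 against M2, 3 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 3.79e-06), and in E1 against E2, 13 were higher and 2 lower (16 and 3 adjusted over the list alone; adjusted p = 0.000578). In E1 against E2, 12 of 32 glutathione S-transferase genes were higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 0.000589). In the same pair, 4 of 15 lipolysis genes were higher and 0 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0495) and 2 of 12 muscle markers were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0132). The M1 minus M2 and E1 minus E2 differences were largely shared (r = 0.817), so the digestive shifts in these pairs are not independent of each other. These lists were not run with an estimated correlation.

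Limma called 787 probe sets between R1 and R2, 357 between M1 and M2 and 1071 between E1 and E2. Within days 1, 2 and 5 alone it called 101, 307 and 134 for R, 7, 146 and 254 for M, with 3 of its 4 arrays on days 1 and 2, and 309, 1004 and 80 for E. The fit without the replicate block of extraction day called 395, 170 and 450 probe sets for R, M and E, and without the arrays of day 2 the counts were 298, 91 and 179. Without day 1 the counts for R and E were 293 and 459, and without the day 1 array of ethanol-exposed E1 the count for E was 709. Without the day 5 array of water-exposed M1 or of ethanol-exposed M2 the count for M was 233 or 232. With the day 5 labels of the variable and ethanol populations of the same number interchanged, chosen after seeing the data, the counts for R, M and E were 1015, 633 and 1652. LManIII and Cyp12d1-d no longer passed between E1 and E2 without day 1 (limma adjusted p = 0.127 and 0.0726) or day 2 (0.248 and 0.189), nor did CG8093 without day 2 (0.102). On day 5 LManIII and CG8093 differed little between E1 and E2. LManIII was then at 1.71 in ethanol and 6.74 in water in E1 and at 1.44 and 6.80 in E2. CG8093 was at 5.47 and 9.13 in E1 and at 4.74 and 8.87 in E2. CG32751 no longer passed between M1 and M2 without day 2 (-2.88, limma adjusted p = 0.116), day 5 (-1.25, 0.195) or the day 5 array of water-exposed M1 (-1.66, 0.082), and within day 1 alone its difference was 0.12 ± 0.33 (0.895). LManIII in ethanol and CG43117 in water lay below the detection level of 4 on average. So did the means over both exposures of CG43117 in M2 and E2 (2.42 and 2.52) and of LManIII in E2 (2.88). The same held for Cyp12d1-d in R2 (3.58) and CAH6 in R1 (3.32). The size of all these differences therefore depends on the background correction.

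Averaged over the 3 days, the variable and ethanol populations of the same number lay closest together, which for M1 and E1 rests on day 5. Limma called 0 probe sets between M1 and E1 (239 at an unadjusted p under 0.05) and 0 between M2 and E2 (332), where the standard deviations of the log2 differences were 0.145 and 0.134. The other 13 pairs of populations had between 357 and 1501 calls and standard deviations from 0.254 to 0.335. Of the probe sets called between M1 and M2 and between E1 and E2, 306 were shared, all with the same sign, against 39.3 for independent lists. The calls between R1 and R2 also exceeded independent lists. They shared 126 with M1 and M2 (106 with the same sign) against 28.9, and 241 with E1 and E2 (199 with the same sign) against 86.6. Across probe sets, which are not independent replicates, the M1 minus M2 and E1 minus E2 differences correlated at r = 0.817, and those with R1 minus R2 at r = 0.302 and 0.297. Without the arrays of day 5 limma called 250 probe sets between M1 and E1 and 28 between M2 and E2, with standard deviations of 0.296 and 0.229. Then r was 0.498, and of 158 shared calls 152 had the same sign. The M1 minus E1 difference of day 5 correlated with that of days 1 and 2 at a mean r of -0.387, below 0 in 6 of 6 pairs of arrays, where days 1 and 2 correlated at 0.332. For M2 minus E2 these means were -0.130, below 0 in 4 of 6, and 0.164, and for the other 13 pairs of populations the mean r of day 5 with days 1 and 2 lay between 0.203 and 0.400. In ethanol-exposed larvae Cyp12d1-d was at 9.12, 8.12 and 3.07 in M1 on days 1, 2 and 5 and at 2.55, 2.89 and 7.34 in E1, and LManIII was at 1.60, 1.66 and 5.79 in M1 and 5.86, 5.07 and 1.71 in E1. These day comparisons were chosen after seeing the data.

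**Figure D4:**
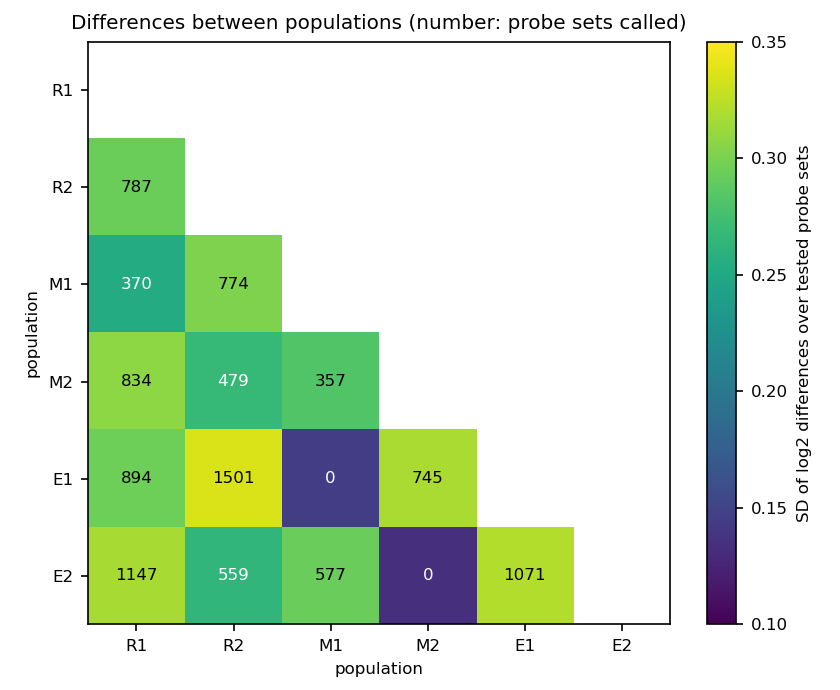
Pairs of the 6 populations (both axes), coloured by the standard deviation of their log2 differences over the tested probe sets and marked with the number of probe sets called. M1 with E1 and M2 with E2 had 0 calls over the 3 days, and 250 and 28 without day 5.

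The last comparison asks whether probe sets that respond to ethanol within a generation also differ between regimes in the same direction. It set the ethanol response of the variable populations against the difference between water-exposed ethanol and control populations, which share no array, over the 665 probe sets called in the variable regime. Across these probe sets r was -0.0931, and 51.6% had the same sign on both sides. In the variable populations Sgs5 rose by 1.83 ± 0.45 and AcCoAS by 0.92 ± 0.10 after ethanol. Between water-exposed ethanol and control populations Sgs5 differed by -0.82 ± 0.22 and AcCoAS by -0.03 ± 0.11, neither passing (limma adjusted p = 0.782 and 0.987). With the control populations split, r was -0.159 (response of R1, difference from R2) and 0.0725 (response of R2, difference from R1). With the control arrays on both sides, over all tested probe sets, r was 0.0528 and the covariance 0.00429, where simulation without any effect gave r = 0.499 and a covariance of 0.0105. The simulation held residual spread alone, without a response to ethanol, so its r cannot be set beside the measured r.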

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

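For 75 probe sets of named genes, each group of 5 or 6 arrays of 1 regime and exposure was searched for an array far from the others, judged by its gap to the nearest array as a share of the whole range of the group. Of 450 groups, 30 held such an array, where chance gives about 22.5 (1 in 20). These groups mix populations and days. No interaction of regime and exposure passed its test, and no data outside the comparisons were left unused.

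The ethanol-exposed M1 array of day 5 accounted for 7 of the 30. There LManIII (5.79 against a median of 1.63 on the other arrays; gap share 0.937), Lip3 (6.84 against 2.00; 0.876), CG12951 (0.848), Amyrel (0.831), CG9672 (0.813) and CG6283 (0.733) were high and Cyp12d1-d was low (0.775). The water-exposed M1 array of the same day was high for CG12951 (gap share 0.771) and low for CG18088 (0.782), CG1774 (0.773) and CG6733 (0.722). On day 5 E1 lay beyond its arrays of days 1 and 2 on the side opposite to M1 in 9 of these 11 cases, 7 of 7 in ethanol and 2 of 4 in water (CG12951 and CG1774), a comparison made after the values were seen. In ethanol LManIII went from 1.60 and 1.66 on days 1 and 2 to 5.79 in M1 and from 5.86 and 5.07 to 1.71 in E1, and Cyp12d1-d from 9.12 and 8.12 to 3.07 in M1 and from 2.55 and 2.89 to 7.34 in E1. In water CG12951 went from 6.01 on day 1 to 10.2 in M1 and from 9.42 and 10.2 to 7.40 in E1. An interchange of arrays is weighed below. The ethanol-exposed E1 array of day 1 was high for CG12951 (0.748) and Amyrel (0.696) and low for CG1774 (0.687) and CG32444 (0.679).

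The ethanol-exposed R2 array of day 1 was low for CG11034 (0.821) and CG1774 (0.781) and high for Cpr65Ec (0.689). The water-exposed R2 array of day 5 was high for Zip102B (0.711) and CG13793 (0.671) and low for RpS7 (0.63). Single arrays of this kind in the control regime were CG13862 (0.718), low in ethanol-exposed R1 of day 1; AcCoAS (0.656), low in ethanol-exposed R1 of day 5; CG32444 (0.629), low in water-exposed R1 of day 1; and Sgs5 (0.707), low in water-exposed R1 of day 2. In the variable regime they were CG18088 (0.728), low in ethanol-exposed M1 of day 1; Grl43a (0.768), high in ethanol-exposed M2 of day 2; and CG13862 (0.763), high in water-exposed M2 of day 2. In the ethanol regime they were Obp99d (0.736), high in ethanol-exposed E1 of day 5, and Npc2e (0.71), low in water-exposed E2 of day 2.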

How the results depend on the processing

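The fits of each extraction day alone, of population number as a block and with the labels of the variable and ethanol populations of the same number interchanged on day 5, and all tests of the pairs M1 with E1 and M2 with E2, were chosen after seeing the data; the other alternatives were planned. Of the named genes that passed their test, 2 had the opposite sign within 1 day alone, CG32751 between M1 and M2 on day 1 (0.12) and Try29F between R1 and R2 on day 5 (-0.11), neither passing there, and none did under the other alternatives. The 23 named values of exposure over all populations kept direction and call under the alternatives fixed in advance wherever they were tested, which was 16 of them under the filter on a mean of at least 6 and 21 with 1 probe set per gene; within day 1 alone 2 of them did not pass. Leaving out 1 day, population or array at a time gave 1797 to 3099 calls for exposure over all populations and 655 to 1865, 169 to 822 and 244 to 876 within the control, variable and ethanol regimes. It gave 0 to 1 for selection of ethanol against control, 0 for the other selection comparisons, and 0 to 20, 0 to 19 and 0 to 1 for the interactions of ethanol against control, variable against control and ethanol against variable. It gave 293 to 830, 91 to 449 and 179 to 1209 for the pairs R, M and E, 0 to 250 for M1 with E1, 0 to 28 for M2 with E2, the highest of these 2 without day 5, and 5 to 7, 2 to 7 and 5 to 9 called lists for exposure, selection and interaction. Fewer arrays were then tested. Values near the GCRMA floor limit what decreases can show.

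With no replicate block, 1029, 335 and 404 probe sets were called within the control, variable and ethanol regimes, 395, 170 and 450 for R, M and E, and 1 for the interaction of variable against control, which had 1 call with robust moderation and 4 with population number as a block. Arrays as replicates gave 767 and 418 calls for ethanol and variable against control, and population as a random block 156 and 81; both count arrays of 1 population as further replicates. Day 1 alone gave 627 calls over all populations, 50, 8 and 17 within the regimes and 101, 7 and 309 for R, M and E. Day 2 alone gave 981, 108 and 419 within the regimes, 307 and 146 for R and M and 1 for the interaction of ethanol against control. Day 5 alone gave 1299 over all populations, 779 and 289 within the control and ethanol regimes, 134 and 80 for R and E, and 5 and 1 for the interactions of variable against control and ethanol against variable. With an estimated correlation 2, 0 and 0 lists were called for exposure, selection and interaction. The r of the response with the regime difference, -0.0931 as reported, was -0.159 and 0.0725 with split controls. It was -0.0232 over all tested probe sets and -0.111 with no filter. With the response of both control populations, where control arrays are on both sides, r was -0.0370 and the covariance -0.0116. Simulation without any effect gave r = 0.492 and a covariance of 0.0162 there. It held residual spread alone, without a response to ethanol, so its r cannot be set beside the measured r. With the day 5 labels interchanged, the r reported as -0.0931 was -0.0748. Limma then called 1220 probe sets within the variable regime, 633 and 1652 for M and E, 498 for M1 with E1 and 65 for M2 with E2. For the interaction of ethanol against control it called 4, phu among them. Lipolysis (interaction, 0.16) and neuron markers (selection, 0.089) then lost their calls, and P450 genes and salivary gland markers (selection, both 0.0434) and ecdysone (0.00342), tracheal and embryonic patterning genes (interaction, both 0.0437) gained one. The causes were not tested.

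Among values that did not pass, 15 of genes and 33 of lists had the opposite sign under an alternative, besides 60 and 64 when a day, population or array was left out; the cause was not tested. For genes (log2), the Adh and Adhr probe set at 13.7 was at -0.015 (median centring) and -0.043 (quantile normalization) in the interaction of variable against control, and at 0.0021 (quantile normalization), 0.00071 (arrays as replicates, and random block) and 0.013 (water-exposed larvae) in selection of ethanol against variable, where the one at 7.40 was at 0.068 in water-exposed larvae. AcCoAS between R1 and R2 was at -0.015 (median centring) and -0.011 (quantile normalization). With the day 5 labels interchanged, the probe set at 7.40 was at 0.041 in selection of ethanol against variable and at 0.055, -0.026 and 0.082 in the interactions of ethanol against control, variable against control and ethanol against variable, where RpS7 was at 0.069 and AcCoAS at -0.13. With arrays, days or populations left out, the probe set at 13.7 ranged from -0.036 to 0.029 (selection, ethanol against variable), -0.025 to 0.042, -0.058 to 0.012 and -0.069 to 0.0041 (interactions of variable against control, ethanol against control and ethanol against variable). The one at 7.40 ranged from -0.11 to 0.064 (selection, ethanol against variable) and -0.27 to 0.14 (interaction, ethanol against control). AcCoAS ranged from -0.042 to 0.070 (R1 against R2), -0.15 to 0.054 (selection, ethanol against control), -0.12 to 0.067 and -0.028 to 0.21 (interactions of ethanol against control and ethanol against variable).

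For lists the values are camera adjusted p. In exposure, cuticle genes turned with no filter (0.556), quantile normalization (0.976) and all probe sets (0.891), salivary gland markers with the stricter filter (0.993) and neuron markers with no replicate block (0.954). In selection, cytosolic ribosomal genes turned with no filter (0.872), ethanol-exposed larvae (0.905), number as a block (0.881) and all probe sets (0.943), FOXO genes with the stricter filter (0.938), water-exposed larvae (0.371) and all probe sets (0.993), and oxidative phosphorylation with median centring (0.788) and water-exposed larvae (0.863). In water-exposed larvae, immune (0.435), cuticle (0.863), alcohol behaviour (0.873) and tracheal genes (0.741) also turned, and in ethanol-exposed larvae glycolysis (0.905). In the interaction, lipid synthesis turned with no filter (0.992) and the stricter filter (0.943), neuron markers with no filter (0.992) and all probe sets (0.944), haemocyte markers with the stricter filter (0.848) and muscle markers with quantile normalization (0.962). Cytosolic ribosomal genes turned there with the stricter filter (0.943), median centring (0.417), no trend (0.92) and an estimated correlation (0.985). With the day 5 labels interchanged, mitochondrial ribosomal genes turned in exposure (0.76), oxidative phosphorylation (0.764) and FOXO genes (0.843) in selection and cytosolic ribosomal genes in the interaction (0.663).

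With a day, population or array left out, the mitochondrial ribosomal list, called in the interaction, ranged from 8.79e-07 to 0.684 and turned without day 1. Of the lists not called that turned, those in exposure ranged from 0.104 to 0.975 (neurons), 0.361 to 0.992 (cuticle), 0.361 to 0.955 (oxidative stress), 0.21 to 0.975 (mitochondrial ribosomal), 0.508 to 0.869 (ecdysone), 0.16 to 0.784 (muscle) and 0.542 to 0.976 (salivary gland). Those in selection ranged from 0.201 to 0.831 (oxidative phosphorylation), 0.229 to 0.975 (UDP-glycosyltransferases), 0.281 to 0.827 (immune), 0.0638 to 0.947 (cuticle), 0.201 to 0.971 (cytosolic ribosomal), 0.671 to 0.998 (FOXO), 0.215 to 0.981 (heat shock), 0.0109 to 0.883 (glutathione S-transferases), 0.173 to 0.981 (ecdysone), 0.173 to 0.919 (trachea), 0.0734 to 0.916 (fat body) and 0.0233 to 0.928 (muscle). Those in the interaction ranged from 0.387 to 0.956 (lipid synthesis), 0.00301 to 0.999 (digestive), 0.0722 to 0.959 (cytosolic ribosomal), 0.141 to 0.701 (oxidative phosphorylation), 0.415 to 0.959 (neurons), 0.00551 to 0.956 (UDP-glycosyltransferases), 0.0715 to 0.774 (muscle), 0.00012 to 0.778 (cuticle), 0.402 to 0.902 (haemocytes), 0.00253 to 0.848 (glutathione S-transferases), 0.0252 to 0.907 (heat shock) and 0.249 to 0.88 (fat body).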

Other observations

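The tests of extraction day, of an interchange on 1 day and of day 5 in general, of arrangements that keep the day, of the pooled contrast and of the pentose phosphate list were chosen after the result was seen. Tested genes of the pentose phosphate pathway, which makes NADPH and ribose phosphate, rose together after ethanol. Zw and Pgd, whose enzymes make its NADPH, had no tested probe set of their own, so those steps were not read. All 5 members with a tested probe set of their own passed, in 6 of 6 populations: Taldo (transaldolase) by 1.17 ± 0.07 and CG8036 (a transketolase gene) by 0.97 ± 0.05. Rpe rose by 0.85 ± 0.09, Pgls by 0.70 ± 0.07 and Rpi by 0.65 ± 0.07, the weakest at limma adjusted p = 1.15e-07. The camera p for this list was 6.9e-10, and it was 0.00379 with an estimated correlation; with a list chosen after seeing the data neither is independent evidence.

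With the ethanol and variable populations pooled against the control populations, a contrast that was not planned, limma called 11 probe sets, 5 higher and 6 lower, with 1233 at an unadjusted p under 0.05. Sgs5 (-1.71 ± 0.14), CG13325 (-1.88 ± 0.19) and Lime (-1.33 ± 0.14) were lower, and QC (0.63 ± 0.06), CG13862 (0.63 ± 0.07) and Phf5a (0.54 ± 0.05) higher. Among the 15 ways to set 2 of the 6 populations against the other 4, 3 gave as many calls, the highest other being 58 for M1 and E1, and 15 ways are too few for a share under 0.05. Over all days the variable and ethanol populations of the same number resembled each other, a pattern that is weighed below.

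The first pattern weighed is that, over all days, M1 resembled E1 and M2 resembled E2. The M1 minus M2 and E1 minus E2 differences correlated 1.46 times as much across days (0.438) as within days (0.301). Among days 1 and 2 alone the ratio was 1.05, from 4 correlations of each kind. These ratios argue against handling of the same numbers together in ways that changed from day to day. Handling that was alike on every day would give such ratios too, so it stays open. A few probe sets are not the reason, since r was 0.712 after leaving out the 185 that differed more than 2-fold. An interchange of M1 and E1 arrays on day 5, or on days 1 and 2, has the values it needs and is a candidate explanation: M1 minus E1 on day 5 correlated at r = -0.387 with days 1 and 2, with arrays of both populations out of place, it would also raise the correlation across days, and day 5 did not act so in general (0.379 for R1 minus R2). For M2 and E2 an interchange stays open at r = -0.130, below 0 in 4 of 6 pairs, and the spread of arrays of these 4 populations, 1.11 times that of control arrays, lay between the bounds set for and against it. With the day 5 labels of both numbers interchanged, the median residual SD fell from 0.193 to 0.183. The M1 minus M2 and E1 minus E2 differences then correlated at r = 0.536, and those with R1 minus R2 at r = 0.401 and 0.204. Of 367 shared calls 351 had the same sign, against 107 shared for independent lists, a level that overlaps with R1 and R2 also exceeded under the given labels. By r, part of the resemblance remained. The values do not show which days would hold the interchanged labels, and a difference between the cultures of the days or a shared origin of populations of the same number was not tested.

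The second pattern weighed is that both exposure and extraction day moved many probe sets, which could reflect a difference in larval age shared by both. The ethanol-minus-water and day 5-minus-day 1 changes correlated across probe sets at r = -0.207, between the bounds set for and against it. Nothing shows that larvae of the 3 days differed in age, so this r cannot decide whether age has a part in the response. Age and exposure cannot be told apart here, because larvae of each exposure were collected as they hatched and hatching times are not used here.

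Other arrangements of the same arrays were counted to ask whether chance could be excluded. With exposure permuted within populations, 1 of 100 arrangements, the real one, gave as many calls as observed over all populations (3037, highest other 2), and likewise in the control (1759, highest other 410), variable (665, highest other 175) and ethanol regimes (820, highest other 189). With population permuted within regime and exposure, 1 of 100 gave as many as the 787, 357 and 1071 calls of R, M and E, where the highest others were 170, 17 and 450. These arrangements did not keep the extraction day. With labels interchanged only between the 2 arrays of a pair on 1 day, 1 of 100 arrangements, the real one, gave as many calls over all populations (highest other 2332, with 1 of 16 pairs interchanged), and 1 of 32 did in the control and ethanol regimes (highest others 482 and 136) and for R and E (141 and 319). In the variable regime and for M, 16 arrangements are too few for a share under 0.05; the real counts were 665 and 357 and the highest others 2 and 18. Chance arrangement of these RNA samples is excluded for exposure over all populations, the control and ethanol regimes, R and E, but the arrays may not come from separate cultures.

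For the selection comparisons chance is not excluded. Of the 45 ways to draw 2 pairs from the 6 populations, 10 gave at least the 920 probe sets at an unadjusted p under 0.05 of ethanol against control, 15 at least the 722 of variable against control and 37 at least the 124 of ethanol against variable. The highest other was 2004, for M1 and E1 against R1 and R2, and M1 and E1 against M2 and E2 gave 1999. All arrangements above 920 set M1 with E1 or M2 with E2 on 1 side, which points to the resemblance within these 2 pairs over all days. For the interactions, 25, 16 and 43 of 45 gave at least the 394, 529 and 211 of ethanol against control, variable against control and ethanol against variable, the highest other being 1380.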
